A study of Homo sapiens with 4 samples.

How the data were processed

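Messenger RNA was sequenced from 4 libraries, 2 with a non-targeting gRNA and 2 with a USP22 gRNA, in fibroblasts differentiated from the H1 stem cell line. Per the labels' protocols, RNA was taken with Trizol and libraries were made with the TruSeq Stranded mRNA kit. The submitters' processing notes name STAR, Salmon, DESeq2 and the build GRCh38. Versions and the annotation release are not given in the sources used here. Per the file headers, 1 deposited table holds TPM values, expected counts and effective lengths per gene for each library, with the column names of a tximport object and counts not scaled by length. TPM values were used only for their sums, which in the deposited table reach 50.1% to 51.0% of the full scale of that unit in each library. Expected counts are those the authors deposited, and they were rounded to whole numbers here. The authors' other deposited table has the columns of a DESeq2 result, per the file headers: the mean normalized count (a signal averaged over all libraries), the log2 fold change with its standard error, the Wald statistic (a score), the p-value and the adjusted p-value. Which counts entered that fit, and its design, are not given in the sources used here. Its sign was read from the count table: all 153 deposited calls among completely counted genes have the same sign in both tables, so a negative log2 value in the deposited table means lower with USP22 gRNA.

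The count table has 55457 rows. The 44 rows for Y copies of the pseudoautosomal region were left out, and 55025 of the other 55413 matched a gene symbol by gene identifier. Coordinates and transcript numbers come from GENCODE 29 on GRCh38, which may differ from the authors' release. Of its 19951 protein-coding genes, 1929 have no row in the count table, *SOX2* among them. To see how much of each gene the count table holds, counts were divided by TMM-scaled library sizes and their mean was divided by the deposited mean normalized count. Of 9896 genes with a deposited mean above 100, 23.7% had a ratio of 0.8 to 1.2 and 24.4% a ratio under 0.05, and the median was 0.298. Genes with a ratio of 0.8 to 1.2 are called completely counted. This set was defined after the data were seen, from means over all libraries and not from differences between groups.

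Groups were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr and a term for the group, and Benjamini-Hochberg adjustment. Calls were made at an adjusted p under 0.05. Standard errors of log2 changes follow from the F statistic. The biological coefficient of variation was 0.403 over the 11341 genes tested and 0.129 over the 4287 completely counted genes. Gene lists and cell type marker lists, fixed before the data were examined, were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01 where 3 or more members were tested. The same lists were tested with cameraPR at that preset correlation on the Wald statistics of the authors' deposited table. In the count table they were also tested with fry and with camera at estimated correlations. Other planned settings were RLE normalization, no count filter, a replicate block, an effective-length offset, leaving out each library, DESeq2 1.42.0, limma-voom, a 2-fold threshold and an adjusted p under 0.01. The completely counted set, its other ratio limits and the comparison with the authors' deposited table were added after the data were seen.

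Genes named by rule, fixed before the data were examined, were *USP22*, the 4 transduced factors, up to 10 genes per direction with the largest change among those with an adjusted p under 0.05, a symbol, at least 5 CPM on average and no overlap of the groups, and up to 4 members with the smallest p per list, 2 to 4 of them printed. Fewer are printed for lists with few completely counted members, and 1 gene that the rule names is not reported here. Genes with a near-identical copy were to be named only with that limit. Count-table values are printed for *USP22*, the factors and genes of the completely counted set, some with the deposited value as well, and only deposited values for other genes. Further genes were chosen after their values were seen, which is stated beside the leading ones and holds for members given only from the authors' deposited table. Counts from libraries of the same group differed by more than sampling noise, with a chi-square per gene of 10.9 with non-targeting gRNA and 13.3 with USP22 gRNA, so no library was merged.

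The tests were tried on simulated counts with the real means, library sizes and trended dispersions, each gene drawn independently. Changed genes were taken only from those above a minimum mean count, so recovery rates do not cover genes with the lowest counts. Over all tested genes, edgeR recovered 11.4% of genes changed by 1 and 54.7% of genes changed by 2 on the log2 scale, with 0 false calls among 10792 genes. Over completely counted genes it recovered 63.2% and 91.9%, with 2 false calls among 4122 genes. A list of raised genes was called in both simulations and 0 of 20 unchanged lists in each. Because the simulated genes were not correlated, this does not show how the list tests behave with correlated genes. Figures were drawn with matplotlib 3.10.9.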

Results

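RNA was sequenced from 4 libraries of human fibroblasts that had been differentiated from H1, an established embryonic stem cell line. The cells expressed Cas9, the nuclease that cuts DNA where a guide RNA (gRNA) directs it, and were transduced with the reprogramming factors OCT4 (gene *POU5F1*), SOX2, KLF4 and MYC. In 2 libraries the cells carried a non-targeting gRNA, and in 2 they carried a gRNA against *USP22*, the ubiquitin protease of the SAGA coactivator complex that removes ubiquitin from histones H2A and H2B. Both groups have replicates numbered 2 and 3, and the series describes them as independent duplicates. The titles carry the number 6 after the letter D, whose meaning the labels do not give. The table of estimated counts summed to 3138469 and 4887253 counts for replicates 2 and 3 with non-targeting gRNA. With USP22 gRNA it summed to 5938424 and 5937525. Compared with the authors' deposited table of differential expression, this table holds only part of the counts of many genes, so these totals are not the sequencing depth. Among 9896 genes with a mean above 100 in the authors' deposited table, 23.7% were completely counted, defined as a scaled mean count within 0.8 to 1.2 times the deposited mean. The comparison of the groups asks which transcripts differ when *USP22* is targeted during reprogramming.

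The targeted gene was lower in both libraries with USP22 gRNA. *USP22* (ENSG00000124422.11) lies on the minus strand of chromosome 17, from 20999593 to 21043760 in GRCh38. Its counts were 1521 and 2018 with non-targeting gRNA and 14 and 3 with USP22 gRNA. In CPM, counts scaled to a common library total, this was 461 ± 49.9 (SD, n = 2) against 1.41 ± 1.30 (SD, n = 2). The summed counts, 3539 against 17, were 323-fold lower once scaled to library size, with an exact binomial 95% interval of 201 to 555 that covers counting error only. The fitted log2 change was -8.33 ± 0.46 (SE), with an adjusted p of 0.091 in edgeR's quasi-likelihood test over all 11341 genes and 2.0e-20 in DESeq2. With an effective-length offset the log2 change was -5.32. The authors' deposited table gives a smaller fall for the gene, a log2 change of -2.20 with a standard error of 0.12 and an adjusted p of 7.9e-70. The count table holds a share of 0.651 of the gene's deposited mean. *USP22* has 11 transcripts in GENCODE 29, and the position of the gRNA target within the gene was not analysed here.

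**Figure D1:**
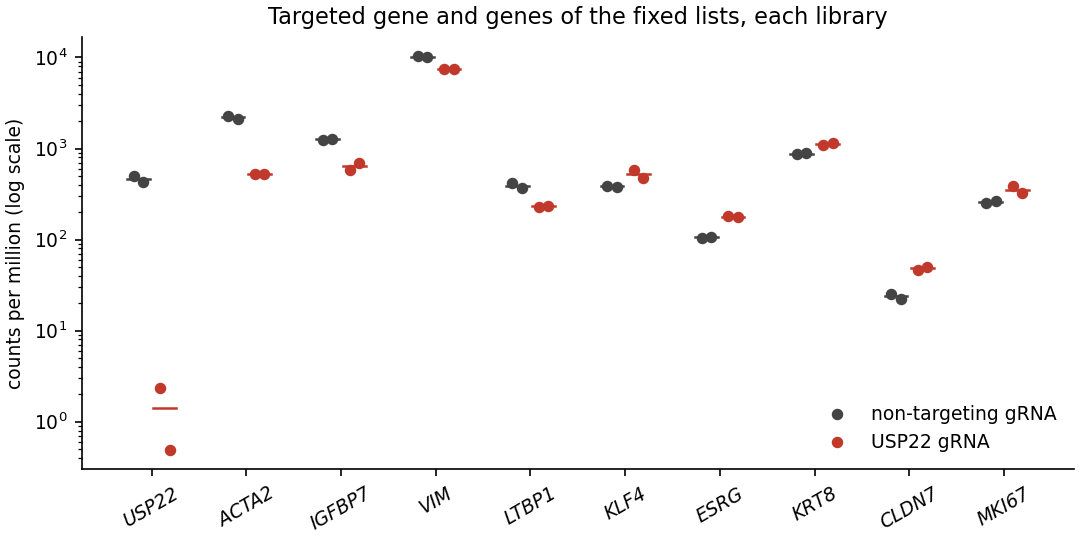
CPM on a log scale for the targeted gene and 9 genes of the fixed lists; each point is 1 library and each bar the mean of the 2 libraries with non-targeting gRNA (grey) or USP22 gRNA (red). *USP22* lies at 496 and 426 with non-targeting gRNA and at 2.33 and 0.493 with USP22 gRNA, and *ACTA2* falls from a mean of 2201 to 524.

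Fibroblast and mesenchymal genes were among those lower with USP22 gRNA, and epithelial and pluripotency genes were among those higher. *ACTA2*, the smooth muscle alpha-actin of myofibroblasts (ENSG00000107796.13, chromosome 10, 88935074 to 88991339 in GRCh38), fell from 2201 ± 111 to 524 ± 6.94 CPM (SD, n = 2 each). Its log2 change was -2.07 ± 0.06 (SE, edgeR adjusted p = 0.035). Leaving out any 1 library ended this call at adjusted p from 0.11 to 0.25, with log2 changes of -2.12 to -2.02. *ACTA2* was the only gene of the 11341 tested that passed in edgeR: 0 genes were higher and 1 was lower. At an unadjusted p under 0.05 there were 1049 genes, where chance gives 567. On the same counts DESeq2 called 194 genes higher and 309 lower, and limma-voom called 0 and 5. Among the 4287 completely counted genes, a set defined after the data were seen, edgeR called 30 genes higher and 59 lower. The largest falls among these with a symbol included *RIMS1*, a presynaptic scaffold protein, with a log2 change of -2.39 ± 0.30, and *OXTR*, the oxytocin receptor, with -1.16 ± 0.14. *PRG4*, the joint lubricant lubricin, changed by -1.89 ± 0.33 and *CLSTN2* by -1.65 ± 0.17 (all SE, edgeR). The largest rises included 2 genes near 0 in the count table with non-targeting gRNA. *HERC3*, a HECT and RCC1-like domain protein, rose there from 0.758 ± 0.774 to 25.2 ± 3.44 CPM. The pseudogene *NPEPPSP1*, whose reads can be shared with its parent gene, had 0 counts in both of those libraries and 7.37 ± 3.68 CPM with USP22 gRNA (SD, n = 2 each). For *HERC3* the log2 change of 5.22 in the count table exceeds the 2.84 of the authors' deposited table. Its low value with non-targeting gRNA may thus be a partial count, since the ratio that defines the set uses means over all libraries. Next came *SLX1A-SULT1A3*, which has a near-identical copy, with a log2 change of 1.71 ± 0.23, and the antisense gene *VPS9D1-AS1*, whose strand assignment is not given in the sources used here, with 1.65 ± 0.27. *PCDH15* had 1.53 ± 0.27, *PRB1*, of a family of similar genes, 1.52 ± 0.23, *ABHD12B* 1.43 ± 0.19, and *MBP*, which encodes myelin basic protein and its Golli variants, 1.22 ± 0.15 (all SE, edgeR). The authors' deposited table, whose input counts are not given in the sources used here, calls 226 genes higher and 442 lower of 13795 with an adjusted p. It holds 46 rises and 74 falls of at least 2-fold. Its largest falls, at a mean normalized count of at least 50, include *MYH11* (log2 -3.96) and *LMOD1* (-2.13), both of smooth muscle, *ACAN* (-2.67), a cartilage proteoglycan, and *SFRP2* (-1.90), a secreted regulator of Wnt signalling. Its largest rises include *HERC3* (2.84), *DNMT3L* (2.26), a cofactor of DNA methyltransferases in germ cells and pluripotent cells, and complement *C3* (2.02). The deposited genes in these sentences, and those above from the completely counted set, were chosen after their values were seen.

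Of the 89 calls among completely counted genes, 77 were also called with the same sign in the authors' deposited table. Of the 503 DESeq2 calls on the count table over all tested genes, 221 were. Both tables come from this series of 4 libraries, so their agreement is no independent support for the calls. The fold changes from both tables had a Pearson correlation of 0.934 across the 4287 completely counted genes. These genes are not independent replicates and were chosen for their agreement in mean level. In the other ranges of the ratio the correlation across genes was 0.325 to 0.481. Leaving out either library with non-targeting gRNA left 0 genes higher and 1 lower in the completely counted set. Without USP22 gRNA replicate 2 there were 9 and 27, and without replicate 3 there were 11 and 22. An effective-length offset gave 12 and 24. Because the labels do not say how the duplicates were made, p-values measure the spread between these libraries.

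**Figure D2:**
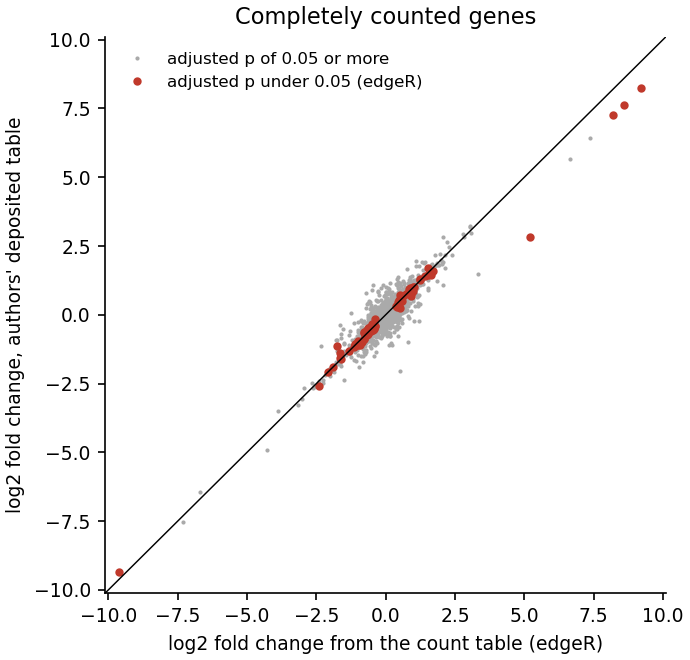
Log2 fold changes of 4287 completely counted genes from the count table (x axis, edgeR) against those in the authors' deposited table (y axis); the line marks equal values. The 89 genes called by edgeR are red, and the correlation across genes is 0.934.

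Fibroblast and mesenchymal genes fell as a group. Single-gene edgeR values given with the gene lists come from the fit of the completely counted genes, except those of *MYC* and *POU5F1*, which come from the fit of all tested genes. Per the authors' deposited table, 24 of 35 members fell and 0 rose (25 fell when adjusted over the list alone). They include *TAGLN* (log2 -1.46), the actin-binding transgelin, and *SPARC* (-0.90), a matrix glycoprotein. Among the 6 completely counted members 5 fell and 0 rose. *VIM*, the intermediate filament of mesenchymal cells, fell from 10230 ± 45.5 to 7511 ± 15.9 CPM (SD, n = 2 each), a log2 change of -0.45 ± 0.05 (SE, edgeR adjusted p = 0.024). Over all 31 members tested in the count table only *ACTA2* passed, and 17 fell when adjusted over the list alone. The list was lower in camera over all tested genes (adjusted p = 1.1e-23), and was not called with an estimated correlation (adjusted p = 0.43). Over completely counted genes camera gave an adjusted p of 3.0e-37, and 0.12 with an estimated correlation. cameraPR on the Wald statistics of the authors' deposited table gave 1.9e-69 at the preset correlation of 0.01. The estimate for this list in the count table was 0.11. All cameraPR values, here and for the lists below, were computed at the preset correlation only, which takes list members as nearly independent. With estimated correlations camera called 0 of 26 lists over all tested genes. This held even for the pluripotency network (camera adjusted p = 0.43), whose estimate of -0.075 lies below the preset one. A call lost at that setting therefore cannot be put down to gene correlation, here or for the lists below.

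TGF-beta response genes also fell in the authors' deposited table, where 8 of 15 fell and 0 rose (9 fell when adjusted over the list alone; cameraPR adjusted p = 1.1e-10). *LTBP1*, which stores latent TGF-beta in the matrix, was completely counted and fell from 391.8 ± 34.8 to 232 ± 4.52 CPM (SD, n = 2 each), a log2 change of -0.76 ± 0.08 (SE, edgeR adjusted p = 0.019). The ligand *TGFB2* has a log2 change of -0.59 in the authors' deposited table. Over all 11 members tested in the count table camera did not call the list (adjusted p = 0.65). Of the senescence genes, 4 of 15 fell and 0 rose per the authors' deposited table (5 fell when adjusted over the list alone), and cameraPR gave an adjusted p of 2.9e-04. *IGFBP7*, a secreted binding protein of insulin-like growth factors, fell from 1263 ± 12.2 to 639 ± 81.8 CPM (SD, n = 2 each). Its log2 change was -0.99 ± 0.10 (SE, edgeR adjusted p = 0.019). *CDKN2B*, an inhibitor of cyclin-dependent kinases that is in both lists, has a log2 change of -0.61 in the authors' deposited table. Of 3 completely counted senescence members only *IGFBP7* passed in edgeR, and their median log2 change was -0.11. Camera called the senescence list lower over these 3 (adjusted p = 0.0020), not with an estimated correlation (adjusted p = 0.29) and not over all 8 tested members (adjusted p = 0.051). Over these 8 members fry called it (adjusted p = 0.0015). Of the BMP response genes 0 of 14 passed in the authors' deposited table, where *ID3* and *MSX2* were among the members without a call. Of the AP-1 factors 1 of 10, *JUN*, fell there (2 when adjusted over the list alone). *FOSB* changed by -0.38 ± 0.14 (SE) in the count table without passing (edgeR adjusted p = 0.24).

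All 4 transduced factors rose in the authors' deposited table. The log2 changes there are 0.55 for *POU5F1*, 0.44 for *KLF4*, 0.35 for *SOX2* and 0.24 for *MYC*, with adjusted p from 0.0040 to 0.025 (4 of 4 also when adjusted over the list alone, cameraPR adjusted p = 4.3e-05). That cameraPR value was computed at the preset correlation, which takes the factors as nearly independent. The correlation estimated in the count table, over 3 tested factors, was 0.60. If the factors shifted together, the cameraPR p-value would be too small, so it is no firm support for a rise of the list. Reads of the factors can come from the transduced copies as well as from the endogenous genes. *KLF4* was completely counted, at 387 ± 7.08 and 526 ± 73.5 CPM (SD, n = 2 each), and its log2 change of 0.44 ± 0.10 (SE) did not pass in edgeR (adjusted p = 0.10). *MYC* had a log2 change of -0.72 ± 0.18 (SE, edgeR adjusted p = 0.40) in the count table, opposite in sign to the authors' deposited table. *POU5F1* had 1.32 ± 0.41 (SE) in the count table, also without passing. That table holds a share of only 0.030 of the deposited mean of *MYC* and 0.035 of that of *POU5F1*, so these 2 values say little. Over 3 tested members, of which only *KLF4* was completely counted, camera did not call the list in the count table (adjusted p = 0.47, and 0.78 with an estimated correlation).

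Pluripotency genes were higher as a group, with members moving both ways. The authors' deposited table has 4 of 23 members higher and 2 lower (the same counts when adjusted over the list alone; cameraPR adjusted p = 0.0034). *ESRG*, a long non-coding RNA of human pluripotent cells, rose from 106 ± 1.26 to 179 ± 5.26 CPM (SD, n = 2 each), a log2 change of 0.74 ± 0.08 (SE, edgeR adjusted p = 0.024 among completely counted genes). *DPPA4* had 0.32 ± 0.08 (SE) without passing (edgeR adjusted p = 0.14). *PODXL*, a surface sialomucin of stem cells that other cells also carry, fell in the authors' deposited table with a log2 change of -0.28. *LEFTY2*, an antagonist of Nodal chosen after its value was seen, fell there too, with -1.15 in the authors' deposited table. The shorter list of undifferentiated stem cell markers, which reprogrammed cells also express, had 2 of 9 members higher and 0 lower in the authors' deposited table (4 higher when adjusted over the list alone, cameraPR adjusted p = 3.9e-05). All 9 are also members of the pluripotency list, without *PODXL* and *LEFTY2*, so the shorter list is no separate support. Camera called both lists higher over all tested genes (adjusted p = 0.0036 and 0.0018), and neither with an estimated correlation (adjusted p = 0.43 for both). Over completely counted genes it called both at an adjusted p of 3.6e-04, and at 0.29 with an estimated correlation.

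Epithelial genes leaned higher in the authors' deposited table, with most members not called. Of 17 members there, 5 rose and 0 fell (the same when adjusted over the list alone, cameraPR adjusted p = 2.6e-04). The other 12, *CDH1* and *EPCAM* among them, had no call. Of the 7 completely counted members 3 rose in edgeR. The tight-junction claudin *CLDN7* rose from 23.9 ± 2.18 to 48.4 ± 2.22 CPM (SD, n = 2 each), a log2 change of 1.02 ± 0.15 (SE, edgeR adjusted p = 0.038). *LSR*, a protein of tricellular junctions, rose by 1.22 ± 0.19 (SE, adjusted p = 0.042). *KRT8*, a keratin of simple epithelia, had 0.34 ± 0.06 (SE) at an edgeR adjusted p of 0.057, and 0.35 in the authors' deposited table, where it passed. Camera called the list among completely counted genes (adjusted p = 2.1e-05), not with an estimated correlation (adjusted p = 0.29) and not over all 17 members tested in the count table (adjusted p = 0.068).

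**Figure D3:**
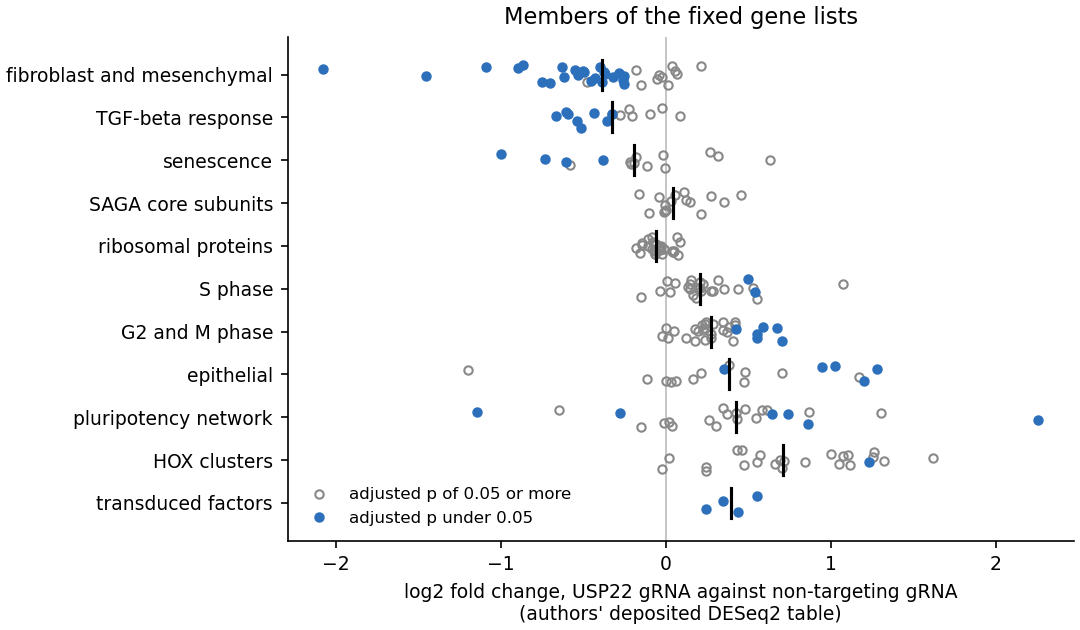
Log2 fold change (x axis, USP22 gRNA against non-targeting gRNA) of each member of 11 gene lists in the authors' deposited table; filled points have an adjusted p under 0.05 and black bars mark list medians. The median is -0.39 for fibroblast and mesenchymal genes, 0.38 for epithelial genes and 0.42 for the pluripotency network.

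Cell cycle genes leaned higher. Of 30 genes of G2 and M phase in the authors' deposited table, 6 rose and 0 fell (11 rose when adjusted over the list alone; cameraPR adjusted p = 2.8e-09), among them *MKI67*, the proliferation antigen, with a log2 change of 0.70. In the count table *MKI67* stood at 257 ± 9.30 and 353 ± 43.3 CPM (SD, n = 2 each), a log2 change of 0.45 ± 0.10 (SE) that did not pass (edgeR adjusted p = 0.092 among completely counted genes). Camera called the G2 and M list higher over all tested genes (adjusted p = 7.1e-04), and not with an estimated correlation (adjusted p = 0.43). Of its 26 tested members only 1, *MKI67*, was completely counted, so this call rests mostly on genes outside that set. Of 26 S phase genes 2 rose and 0 fell in the authors' deposited table (3 rose when adjusted over the list alone; cameraPR adjusted p = 1.4e-04). Over 17 members tested in the count table camera did not call the S phase list (adjusted p = 0.12, and 0.78 with an estimated correlation). The replication helicase subunit *MCM4* has a log2 change of 0.54 in the authors' deposited table. *E2F8* had 0.97 ± 0.40 (SE) in the count table without passing (edgeR adjusted p = 0.29). Of 24 HOX genes 23 have a positive log2 change and 1, *HOXA9*, rose in the authors' deposited table (3 rose when adjusted over the list alone; median 0.71, cameraPR adjusted p = 9.1e-05). *HOXA10* stood at 22.4 ± 6.79 and 40.4 ± 1.81 CPM (SD, n = 2 each), a log2 change of 0.82 ± 0.23 (SE, edgeR adjusted p = 0.16). Camera called the HOX list over 6 completely counted members (adjusted p = 0.021), not with an estimated correlation (adjusted p = 0.29) and not over all 15 tested members (adjusted p = 0.15).

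Other subunits of SAGA did not pass. Besides *USP22*, 0 of the 7 other measured members of the deubiquitinase list and 0 of 16 acetyltransferase and core subunits passed in the authors' deposited table. *ATXN7L3*, the adaptor that the deubiquitinase needs, had a log2 change of 0.14 ± 0.07 (SE, edgeR adjusted p = 0.39) and *ENY2* of 0.16 ± 0.08 (SE, adjusted p = 0.39). *TAF5L*, a core subunit, had 0.30 ± 0.15 (SE, adjusted p = 0.37). The deubiquitinase list includes *USP22* itself, with a log2 change of -2.20 in the authors' deposited table. There, 6 of its 8 members are positive, with a median of 0.15 and a mean of -0.01, while cameraPR points down (adjusted p = 0.088). The list was not tested without *USP22*, so this direction cannot be read as a fall of the other subunits.

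The remaining lists had few calls or none. The authors' deposited table has 4 of 20 glycolysis genes lower, among them the pyruvate kinase *PKM* (log2 -0.21), and 0 higher (5 lower when adjusted over the list alone), with a cameraPR adjusted p of 0.13. Of 14 hypoxia genes 1, the collagen prolyl hydroxylase *P4HA2*, fell in the authors' deposited table. In the count table *P4HA2* fell by a log2 change of -0.43 ± 0.07 (SE, edgeR adjusted p = 0.042 among completely counted genes). Camera called the hypoxia list lower over 3 completely counted members (adjusted p = 0.0020), not with an estimated correlation (adjusted p = 0.34). Over all 11 tested members the median was 0.02 and camera did not call the list (adjusted p = 0.67). Of 24 p53 targets 2 fell, *CDKN1A* and *PLK2*, and 0 rose in the authors' deposited table. In the count table *EDA2R* had a log2 change of -3.01 ± 0.65 (SE, edgeR adjusted p = 0.092), at 3.42 ± 1.14 and 0.413 ± 0.114 CPM (SD, n = 2 each), and *SESN1* had 0.64 ± 0.16 (SE, edgeR adjusted p = 0.14). Of 27 interferon response genes 1 rose (*MX1*) and 1 fell (*BST2*), and of 31 Polycomb and chromatin regulators 1 rose (*BMI1*) and 1 fell (*PCGF2*), in the authors' deposited table. Of 22 cholesterol synthesis genes, 19 stress response genes and 30 ribosomal protein genes 0 passed in the authors' deposited table. Adjusted over the list alone, the authors' deposited table gives the same counts for the 7 lists from hypoxia to ribosomal proteins. *HMGCS1* had 0.16 ± 0.07, *SLC7A11* 0.22 ± 0.06 and *DDIT3* -0.28 ± 0.09 (log2, SE) in the count table, with edgeR adjusted p from 0.17 to 0.30.

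Markers of other cell types and of RNA quality were measured beside these groups. Of 3 muscle cell markers with an adjusted p in the authors' deposited table all 3 fell (*MYH3*, *ACTC1* and *DES*; cameraPR adjusted p = 1.4e-04), in the same direction as the mesenchymal genes, and 0 muscle markers were tested in the count table. Of 4 neural markers 1, *STMN2*, rose in the authors' deposited table. Of 7 endothelial, 3 endoderm, 8 keratinocyte and 2 blood cell markers 0 passed in the authors' deposited table. Adjusted over the list alone, 1 endothelial marker was higher, 1 endoderm marker lower and, beside *STMN2*, 1 neural marker lower in the authors' deposited table. In the count table *MAP2* had 0.27 ± 0.14, *AFP* 0.44 ± 0.22, *ITGB4* 0.23 ± 0.14 and *HBA1*, which has the near-identical copy *HBA2*, 0.57 ± 0.23 (log2, SE), with edgeR adjusted p from 0.28 to 0.46. Mitochondrially encoded genes took 17.4 ± 0.813% of the counts with non-targeting gRNA and 19.0 ± 0.571% with USP22 gRNA (SD, n = 2 each). Of these 13 genes 1, *MT-ND4L*, rose in the authors' deposited table (2 when adjusted over the list alone; cameraPR adjusted p = 0.044), and camera did not call them in the count table (adjusted p = 0.11). Of 11 heat shock genes 2 rose (*HSPD1* and *HSP90AA1*) and 1 fell (*HSPB1*) in the authors' deposited table.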

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

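Results for completely counted genes, other ratio limits and the authors' deposited table were chosen after seeing the data; the other settings were planned. The count of 0 genes higher became 194 with DESeq2, 30 over completely counted genes and 226 in the authors' deposited table, and stayed 0 under the other settings. The count of 1 gene lower became 0 with the replicate block, 2 with the effective-length offset, 309 with DESeq2, 5 with limma-voom, 0 at an adjusted p under 0.01, 59 over completely counted genes and 442 in the authors' deposited table. Without any 1 library, 0 genes were higher and 0 lower, the lone library being assumed to vary like the other group. For completely counted genes, the 30 higher became 16 with the replicate block, 12 with the length offset, 53 with DESeq2, 0 at a ratio of at least 0.5, 47 at a ratio of 0.9 to 1.1, 12 at 2-fold and 0 at an adjusted p under 0.01, with 0 to 11 on leaving out a library. The 59 lower became 24 with the length offset, 98 with DESeq2, 7 at a ratio of at least 0.5, 15 at 2-fold and 1 at an adjusted p under 0.01, with 1 to 27 on leaving out a library, 45 with the replicate block and 74 at a ratio of 0.9 to 1.1. *USP22* ranged from -9.79 to -7.62 without a library, passed in DESeq2 at -8.36 and in the authors' deposited table at -2.20, and was -8.36 with the replicate block (adjusted p = 0.56). Of 26 lists, 4 were called; this became 0 with estimated correlations, 1 with fry, 7 of the 15 lists testable over completely counted genes, 12 of the 29 testable with cameraPR on the authors' deposited table, 1 to 7 without a library (1 without non-targeting gRNA replicate 3) and 4 with the replicate block. The 1 list called with fry was the senescence list (adjusted p = 0.0015), which is not among the 4 called by camera. Of those 4, the pluripotency list and the stem cell marker list overlap, so their calls are not separate. Same-numbered libraries deviated together with a correlation of 0.057 across all tested genes and 0.047 across completely counted genes. This gave no sign that the numbers pair the libraries, but a check of 2 pairs cannot exclude it. *ACTA2*, the 1 gene lower, kept a log2 change of -2.07 with the replicate block (adjusted p = 0.40) and of -2.12 to -2.02 without a library, where it no longer passed. *MYC* reversed from -0.72 to 0.24 in the authors' deposited table, and *HNF4A*, at about 2 CPM and in the fit of all tested genes, from 0.18 to -0.62 with the length offset and -0.76 in the authors' deposited table. The cause was not tested, except that fewer genes or libraries enter some settings. Partial counts limit all genes outside the completely counted set.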

Other observations

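Some other genes of smooth muscle contraction, picked after their values and those of *MYH11* and *ACTA2* were seen and so no test of the group, fell in the authors' deposited table. They are the gamma-actin *ACTG2* (log2 -2.20), the myosin light chain *MYL9* (-1.04), calponin *CNN1* (-1.16) and *MYOCD* (-1.51), the coactivator of smooth muscle genes, all from the authors' deposited table. *SYNPO2* (-0.54), looked up with them, had no call in the authors' deposited table. Among other genes that rose there are *UCP1* (1.77), the uncoupling protein of brown fat, and *AIRE* (1.78), a transcriptional regulator of the thymus, per the authors' deposited table. *SLX1A-SULT1A3* is higher (1.59) while its near-identical copy *SLX1B-SULT1A4* is lower (-1.22) in the authors' deposited table, so reads shared between the copies leave both uncertain.

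Tests of the partial counts, of equal falls among fibroblast genes and of the 4 factors, and repeated thinning with its use for the epithelial, pluripotency and G2 and M lists, were chosen after the results were seen; the other tests below were set before. The count table holds less of many genes than the deposited mean normalized count does. Among genes with a deposited mean above 100, the 140 with 1 annotated transcript had a median ratio of 0.9999, while the 9756 with more had a median of 0.287. This is what a table without part of the transcripts would give. Fewer reads behind the table would lower all genes alike, yet 23.7% of genes were held completely. No biological explanation was tested.

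With an effective-length offset, *USP22* fell by a log2 change of -5.32 in the count table, against -2.20 in the authors' deposited table. Without the offset the gap was larger. In that fit, the fall of *USP22* was larger by 6.13 log2 units in the count table than in the authors' deposited table. Of 599 genes with a similar ratio (0.5 to 0.8) and a deposited mean of at least 500, 0 differed by as much (0%), and the largest difference was 1.76. These genes were not matched to *USP22* on having a group near 0 counts, where log2 differences can be larger. The comparison therefore cannot decide on the scatter of partly counted genes. From the mean and fold in the authors' deposited table, the normalized count would be 2800 with non-targeting gRNA and 610 with USP22 gRNA, or 21.8% left. Subtracting the scaled counts of the count table (2214 and 6.77) leaves 586 and 603 outside it, a ratio of 1.03. This subtraction takes both tables to be on 1 scale and leaves effective lengths out. Those of *USP22* were 4718 and 4540 with non-targeting gRNA and 345 and 876 with USP22 gRNA. If the deposited counts were adjusted for length, the counts outside the table would differ from these. A candidate explanation is that the *USP22* reads left with USP22 gRNA belong to transcripts that are not in the count table; counts per transcript were not analysed here, so altered transcripts and reads assigned differently after editing cannot be told apart.

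Mesenchymal genes were lower while epithelial, pluripotency and cell cycle genes leaned higher with USP22 gRNA. A lower share of fibroblasts with nothing else changed would lower by 1 factor those genes that only the fibroblasts express. The 35 list members differed by far more than their standard errors in the authors' deposited table (heterogeneity p = 7.4e-181, quartiles -0.58 and -0.17, against -2.08 for *ACTA2*). If other cells also express some members, a lower share would give unequal falls too. This test therefore cannot decide, and a lower share of fibroblasts stays open. With all libraries thinned to 3138430 counts, the fibroblast list had a median of -0.41 (-0.43 before; -0.47 to -0.40 in 20 further draws) and was called in each draw at the preset correlation, though in 0 of 20 with an estimated one, and the G2 and M list likewise had medians of 0.36 to 0.50 (0.42 before) with calls in 20 and 0 of 20, which argues against unequal totals for these genes. Unequal totals stay open for the epithelial list, not called at full totals, with medians of -0.11 to 0.29 over the draws (0.12 in the middle; 0.07 in the first thinning, not called, and 0.16 before) and calls in 10 of 20, and for the pluripotency list, with medians of 0.29 to 0.63 and calls in 18 of 20 (0.71 in the first thinning, called at an adjusted p of 0.015, and 0.59 before), both with 0 of 20 at an estimated correlation. The 4 transduced factors were higher by a mean log2 of 0.40 in the authors' deposited table, so a larger dose of factors may contribute; vector and endogenous transcripts cannot be told apart in these tables, and an effect of *USP22* loss itself also stays open.

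A cut on chromosome 17 might lead to loss of the arm beyond it in part of the cells. The 225 genes between the short-arm end and *USP22* had a lower median log2 change than the 13520 other genes in the authors' deposited table (difference -0.062; 2-sided permutation test over genes with 100000 resamples, p = 0.0066). Neighbouring genes are not independent, and in a comparison added after that p was seen, of 50 blocks of 225 neighbouring genes elsewhere, 12 lay as far from 0 and 6 as low, the lowest at -0.12. A small arm loss and regional variation cannot be told apart.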
